A study of Homo sapiens with 945 samples.

How the data were processed

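Protein levels were measured by reverse phase protein array, in which lysates are spotted on slides and each slide is probed with 1 antibody. The samples were culture dishes from 21 cell lines, with 15 conditions per line and 3 dishes per condition. Per the labels, cells were starved of serum for 24 h and then received 10 nM IGF1 or 10 nM insulin for 5, 10 or 30 min or 6, 24 or 48 h. Dishes kept in serum-free medium without ligand were labelled 5 min, 24 h and 48 h. Per the labels' protocols, each lysate was arrayed in 5 serial dilutions on nitrocellulose, and bound antibody was amplified and visualised with a brown colour reaction.

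The deposited table gives 1 log2 value per antibody and dish, called raw data (Superlog2) per the file headers. Neither the headers nor the labels state how a dilution series became 1 value, or whether loading was corrected. The deposited log2 values ran from -6.60 to 5.72, with 0 missing values and 0 identical columns. The table holds 134 antibodies, of which 38 are phospho-specific by name and 96 are not. Its quality column marks 108 antibodies Y and 26 N, and all 134 were kept. The file's gene names gave 92 symbols, of which 91 were found in the supplied human gene table.

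The values were corrected for protein loading as follows. Each antibody was centred on its median over all dishes, and the median over antibodies of a dish was taken as its loading offset and subtracted. Offsets ran from -2.09 to 1.34 log2. After correction, the SD between the 3 dishes of a group had a median of 0.13 log2 over antibodies, with a range of 0.07 to 0.27. Array signal has no count of molecules behind it, so precision is limited by the number of dishes and lines.

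The cell line was the replicate for comparisons over lines (n = 21 lines), and all 21 were treated as independent. Whether any lines share an origin was not tested, and related lines would make p-values over lines too small. The 3 dishes of a group were averaged, the difference between conditions was taken per line, and limma 3.58.1 in R 4.3.3 tested its mean against 0 with a moderated variance. Adjusted p-values are Benjamini-Hochberg over the 134 antibodies, two-sided, with a threshold of 0.05. Errors of means over lines are the moderated SE. The early window is the mean of 5, 10 and 30 min minus serum-free 5 min. The 6 h dishes were also compared with serum-free 5 min, since no serum-free 6 h dishes exist. The late window is the mean of 24 and 48 h minus serum-free dishes of the same times.

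Within each line, limma was fitted to its 45 dishes in 15 groups. Differences between lines were tested with limma's F-test over all 315 groups. Antibodies were also grouped into 15 lists, and each list's mean per line was tested with a two-sided sign-flip permutation test over 21 lines (100000 resamples), adjusted over the lists of a comparison. Correlations over lines used permutation p-values. Where a measure split the lines by a gap of over 25% of its range, the correlation was computed within each group of lines. The measure that split was the response each time, so these correlations cannot show a difference between the groups; baseline levels were therefore also compared between the 2 groups with an exact permutation test of lines, two-sided, added after seeing the data and adjusted over 4 tests. The rule for naming antibodies took those past the threshold with the mean's direction in at least 15 lines, up to 10 per direction and comparison. It also took all members of the receptor and adaptor, PI3K-Akt, mTOR-S6K and MAPK lists. The design, the lists, the naming rule and most alternatives were fixed before the data were examined.

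Tests were run on simulated data in which antibodies were shifted by known amounts over the real spread of the 134 antibodies. This covered the test over lines for 4 of the 10 comparisons, the tests within lines and between lines, and the list test; the baseline F-test was run on unshifted data alone, and the correlations were not simulated. The early IGF1 comparison recovered 55.0% of shifts of 0.1 log2, 95.8% of 0.3 and 99.8% of 1, and 6.79% of its calls were false. For IGF1 minus insulin at early times 88.5% of shifts of 0.1 were recovered. The F-test for early IGF1 changes gave 23.7% false calls when lines differed in spread, so a Welch version in which each line keeps its own spread (6.78% false) was added as an alternative.

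The alternatives covered no loading correction, loading by total proteins or by the mean, and leaving out the weakest 25% of antibodies. They also covered medians of dishes, 1 fit of all line means, a sign-flip test, each replicate number or each line left out, and other control dishes. Another setting kept replicates separate. For comparisons over lines it took differences per replicate number, with the line as block and 1 correlation shared by all antibodies. Dishes then count in part as replicates, which can raise the number of calls. Within lines and between lines the replicate number itself was the block. Restricting to antibodies marked Y and leaving out 19 dishes whose loading offset lay over 1 log2 from their line's median were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.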

Results

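The level of 134 proteins and phosphorylated sites was measured in 21 cell lines that the labels describe as breast cancer, before and after stimulation with IGF1 or insulin. Both hormones act through related receptor tyrosine kinases, and the study's title asks for signals that differ between them. Each line contributed 3 dishes to each of 15 conditions. MCF10A is an immortalised mammary epithelial line that does not form tumours. The other names are kept as the labels give them, and the origin of the lines was not tested. Antibody names are those of the file, with the phosphorylated residue last, and changes are log2 values corrected for loading (± SE over lines, n = 21 lines). Dishes are separate cultures per the labels, and p-values for means rest on lines, not dishes.

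Before stimulation the lines differed widely in receptor and adaptor proteins. Of 134 antibodies, 133 differed between lines in the serum-free 5 min dishes by limma's F-test. IGFR1B, the beta chain of the IGF1 receptor, was highest in MCF7 at -0.30 ± 0.05 (SD, n = 3 dishes) and lowest in SKBr3 at -2.35 ± 0.08. IRB, the insulin receptor beta chain, was highest in ZR75-1 at 0.20 and MDA-MB-468 at 0.18, and lowest in HCC60 at -2.06. IRS1, the adaptor that links both receptors to PI3 kinase, ranged from 3.46 in MCF7 to -0.37 in BT20. PTEN, the phosphatase that opposes PI3 kinase, was highest in T47D at 1.86 and lowest in MDA-MB-468 at -2.10. Basal AKT_pS473 was highest in HCC1954 at 1.69 and MDA-MB-468 at 1.68, and lowest in MDA-MB-134 at -2.72, a range of 4.42 log2. Among luminal proteins, the progesterone receptor (PR) reached 3.82 in T47D against a median of -3.72, and GATA3 reached 3.49 in MCF7. HER2 was highest in HCC1954 at -0.40, AU565 at -0.47 and BT474 at -0.70, and lowest in the dishes labelled MDA-MB-453 at -3.38. Dishes labelled MDA-MB-231, MDA-MB-415 and MDA-MB-453 lay close together in IRS1 (1.55, 1.50 and 1.51) and PTEN (0.74, 0.86 and 0.68). They were less close in EGFR (1.03, 1.06 and 1.40) and Cyclin.D1 (0.07, 0.12 and -0.35). The identity of the lines was not tested. EGFR was highest in MDA-MB-468 at 3.72. The androgen receptor (AR) was highest in MDA-MB-361 at 1.07 ± 0.05 (SD, n = 3 dishes) and T47D at 1.02 ± 0.22, E.Cadherin in MDA-MB-361 at 1.61 and T47D at 1.54, p53 in MDA-MB-415 at -0.58 ± 0.13 and MDA-MB-231 at -0.70 ± 0.09, Cyclin.D1 in MDA-MB-134 at 1.58, ER_pS118 in MDA-MB-134 at 1.25, and AKT_pT308 in AU565 at 0.59 ± 0.21 and SKBr3 at 0.53 ± 0.20. N.Cadherin stood at -2.35 ± 0.95 in MDA-MB-453, whose dishes differed widely, and at -2.48 ± 0.11 in AU565.

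IGF1 raised the signal of the phosphorylated IGF1 receptor antibody early in every line; whether this antibody also detects phosphorylated insulin receptor stays open. Over the early window (5, 10 and 30 min against serum-free 5 min), IGFR1_pY1135 rose by 1.46 ± 0.11, or 2.76-fold, in 21 of 21 lines (limma adjusted p = 3.13e-10). The kinase Akt followed at both activating sites. AKT_pS473 rose by 1.42 ± 0.33 in 16 lines (adjusted p = 0.0177), and AKT_pT308 by 0.71 ± 0.19 in 19 lines (adjusted p = 0.0249). GSK3ab_pT21, the inhibitory site of GSK3 that Akt phosphorylates, rose by 0.26 ± 0.07 in 18 lines (adjusted p = 0.0261). The transcription factor sites STAT5_pY694 and STAT6_pY641 rose as well, by 0.66 ± 0.16 in 19 lines and 0.26 ± 0.07 in 15 (limma adjusted p = 0.0215 for both). The file's quality column marks both antibodies N. Other such sites, among them STAT3_pY705, STAT3_pT727, SMAD3_pS423 and c.JUN_pS73, did not pass. SMAD3, a mediator of TGF-beta signalling, was the 1 antibody that fell, by 0.07 ± 0.02 in 18 lines (limma adjusted p = 0.0232). Within lines SMAD3 was called lower in 3 with early IGF1 and in 4 with early insulin, so this fall is not shown to be particular to IGF1.

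In all, 6 antibodies rose and 1 fell early with IGF1, and 21 had an unadjusted p under 0.05. Of the 5 PI3K-Akt phosphorylation antibodies 3 rose, or 4 adjusted over the list alone, and the list's mean rose by 0.51 ± 0.13 (permutation adjusted p = 0.00757). The other 2 were TSC2_pT1462 at 0.18 (adjusted p = 0.131) and PDK1_pS241 at -0.03. The receptor and adaptor list rose by 0.19 ± 0.02 through IGFR1_pY1135 alone among its 7 members (1 adjusted over the list alone), while its member median was -0.01. IRS1, IRS1_pS307, IGFR1B, IRB, IRB_2 and IGFBP2 had means between -0.05 and 0.00. In the Src-STAT-FAK list 2 of 11 members rose (2 adjusted over the list alone); its mean rose by 0.07 ± 0.02 against a member median of -0.03 (adjusted p = 0.0267). None of the 6 mTOR-S6K antibodies passed, and S6_pS240, a ribosomal protein site downstream of mTOR, stood at 0.28 ± 0.11 (adjusted p = 0.178). S6_pS235 stood at 0.22 and p70S6K_pT389 at 0.20, and the 3 4EBP1 sites lay between -0.04 and 0.01. None of the 3 MAPK antibodies passed. MAPK_pT202, the activated form of ERK1 and ERK2, stood at -0.07 ± 0.16, MEK12_pS217 at -0.06 and p90RSK_pT359 at 0.01.

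Means of the energy sensing list (-0.06 ± 0.02) and of the adhesion and mesenchymal list (-0.04 ± 0.01) fell early with IGF1 (permutation adjusted p = 0.0149 for both), with 0 members called over all antibodies and 2 and 1 adjusted over the list alone. Both means turned positive, 0.04 and 0.06, without the loading correction, and did not pass with loading by total proteins (adjusted p = 0.0923 and 0.282). The Src-STAT-FAK mean did not pass without any 1 of BT474, MCF7, MCF10A, MDA-MB-134, MDA-MB-231 or MDA-MB-415 (up to 0.0542). The remaining list means did not pass in this window. These were mTOR-S6K at 0.11, MAPK at -0.04, stress kinases at -0.05, ErbB receptors at 0.01, PKC at -0.03, and cell cycle at -0.02. Apoptosis and survival stood at -0.02, steroid receptors and luminal proteins at 0.00, DNA damage and p53 at -0.01 and total pathway kinases at -0.04.

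**Figure D1:**
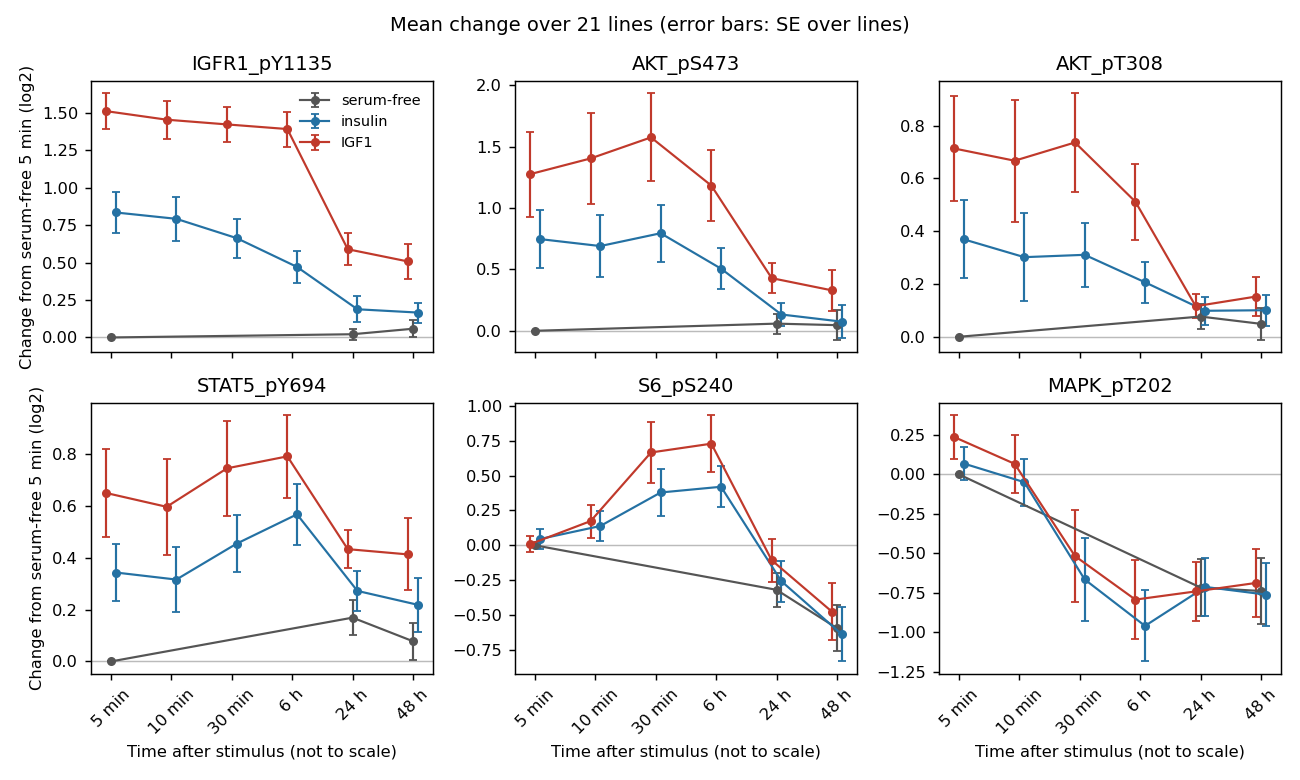
Mean log2 change from serum-free 5 min over 21 lines (y axis) by time after stimulus (x axis, not to scale) for 6 antibodies; red is IGF1, blue insulin, grey serum-free medium, and bars are the SE over lines. IGFR1_pY1135 stood 1.51 log2 above the control at 5 min of IGF1 and 1.39 at 6 h, and MAPK_pT202 was -0.72 in serum-free dishes at 24 h without any ligand.

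Loading moved with the early stimulus. The loading offset rose by 0.10 ± 0.05 with IGF1 (permutation p = 0.0474, n = 21 lines), and without its removal the median of all antibodies stood at 0.09; the changes above are relative to that shift. Without the correction 9 rose and 0 fell, with the mean as the loading measure 6 rose and 7 fell, and with replicates kept separate 10 rose and 4 fell. SMAD3 turned to 0.04 without the correction, and its call also ended with loading by total proteins (adjusted p = 0.122), medians of dishes (0.166), without replicate 2, with 1 fit of all line means (0.147) or with the mean of 3 serum-free times as control (0.218). Without ZR75-1 4 antibodies were called; AKT_pT308 and SMAD3 then had adjusted p = 0.0517. GSK3ab_pT21 lost its call without any 1 of MCF7, MDA-MB-231, MDA-MB-415 or ZR75-1 (adjusted p up to 0.0581). With the mean of all 3 serum-free times as control 36 antibodies were called (13 up, 23 down), MAPK_pT202 among them at 0.41, and STAT6_pY641 was not (adjusted p = 0.194).

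Insulin also raised the signal of the receptor antibody in most lines. Early IGFR1_pY1135 rose by 0.76 ± 0.12, or 1.70-fold, in 20 of 21 lines (limma adjusted p = 0.000353), from -0.08 in MCF10A to 2.56 in MDA-MB-468. It was the 1 antibody of 134 past the threshold, with 12 at an unadjusted p under 0.05. AKT_pS473 stood at 0.74 ± 0.21 in 17 lines (adjusted p = 0.0675), AKT_pT308 at 0.33 (adjusted p = 0.303), GSK3ab_pT21 at 0.16 and STAT5_pY694 at 0.37 (adjusted p = 0.0592). Adjusted over the list alone, 3 of 5 PI3K-Akt antibodies rose, against 0 over all antibodies, and the list's mean stood at 0.25 ± 0.09 (permutation adjusted p = 0.0574). The receptor and adaptor list rose by 0.10 ± 0.02 (permutation adjusted p = 3e-04), with a member median of -0.01. S6_pS240 stood at 0.19, MAPK_pT202 at -0.21 ± 0.13 and IRS1 at 0.06, none past the threshold. The loading offset was 0.12 ± 0.05 higher than in the same control dishes (permutation p = 0.0188, n = 21 lines), and the median of all antibodies without correction was 0.11. Without the correction 7 rose and 0 fell, with the mean as loading measure 1 rose and 1 fell, and with replicates kept separate 6 rose and 1 fell. The count was 4 without AU565 or HCC1569, and 2 without HCC1954, MCF7, MDA-MB-468 or replicate 1. With the mean of all 3 serum-free times as control 5 rose and 9 fell, in 1 fit of all line means 3 rose and 1 fell, and the sign-flip test called 2.

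Set directly against insulin over the early window, IGF1 gave higher mean levels along the receptor-Akt axis, but no single antibody passed the threshold. IGFR1_pY1135 was 0.70 ± 0.18 higher with IGF1 in 18 of 21 lines (95% interval 0.33 to 1.07), AKT_pS473 0.67 ± 0.19 in 15 lines and GSK3ab_pT21 0.10 ± 0.03 in 16 lines (limma adjusted p = 0.0853 for each). With limma 0 antibodies were called, 15 had an unadjusted p under 0.05, and the sign-flip permutation test called 0. Taken as a list, PI3K-Akt phosphorylation was 0.25 ± 0.07 higher with IGF1 (permutation adjusted p = 0.0167), and 4 of its 5 members passed adjusted over the list alone. The receptor and adaptor list was 0.09 ± 0.02 higher (adjusted p = 0.0167) and the Src-STAT-FAK list 0.03 ± 0.01 higher (adjusted p = 0.0343), each with a member median just below 0. The apoptosis and survival list was lower, at -0.02 ± 0.01 (adjusted p = 0.0343). Only the PI3K-Akt list passed without the loading correction (0.186, 0.487 and 0.426 for the others); the apoptosis list also ended with loading by total proteins (0.374), and the last 2 lists without any 1 of 9 and 8 lines (up to 0.0709). Single antibodies were called without BT474 (3), Cama1 (1), MDA-MB-468 (1) or replicate 1 (2), and 5 were called in 1 fit of all line means. With replicates kept separate, where dishes count in part as replicates, 11 were called (10 higher, 1 lower).

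Taken time by time, antibodies passed between the hormones at 30 min and 6 h alone. At 30 min 6 antibodies were higher with IGF1 and 0 lower. AKT_pS473 was 0.78 ± 0.19 higher and IGFR1_pY1135 0.76 ± 0.17 (limma adjusted p = 0.0148 for both). AKT_pT308 was 0.43 higher, S6_pS240 0.29, S6_pS235 0.25 and GSK3ab_pT21 0.12. At 6 h IGFR1_pY1135 was 0.92 ± 0.14 higher in 20 lines (adjusted p = 0.000172) and AKT_pS473 0.68 ± 0.17 in 17 lines (adjusted p = 0.0328). No antibody passed at 5, 10 min, 24 or 48 h, with 6, 8, 10 and 17 at an unadjusted p under 0.05 by limma. Whether the difference changed with time was not tested, so the times that passed do not date its start.

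**Figure D2:**
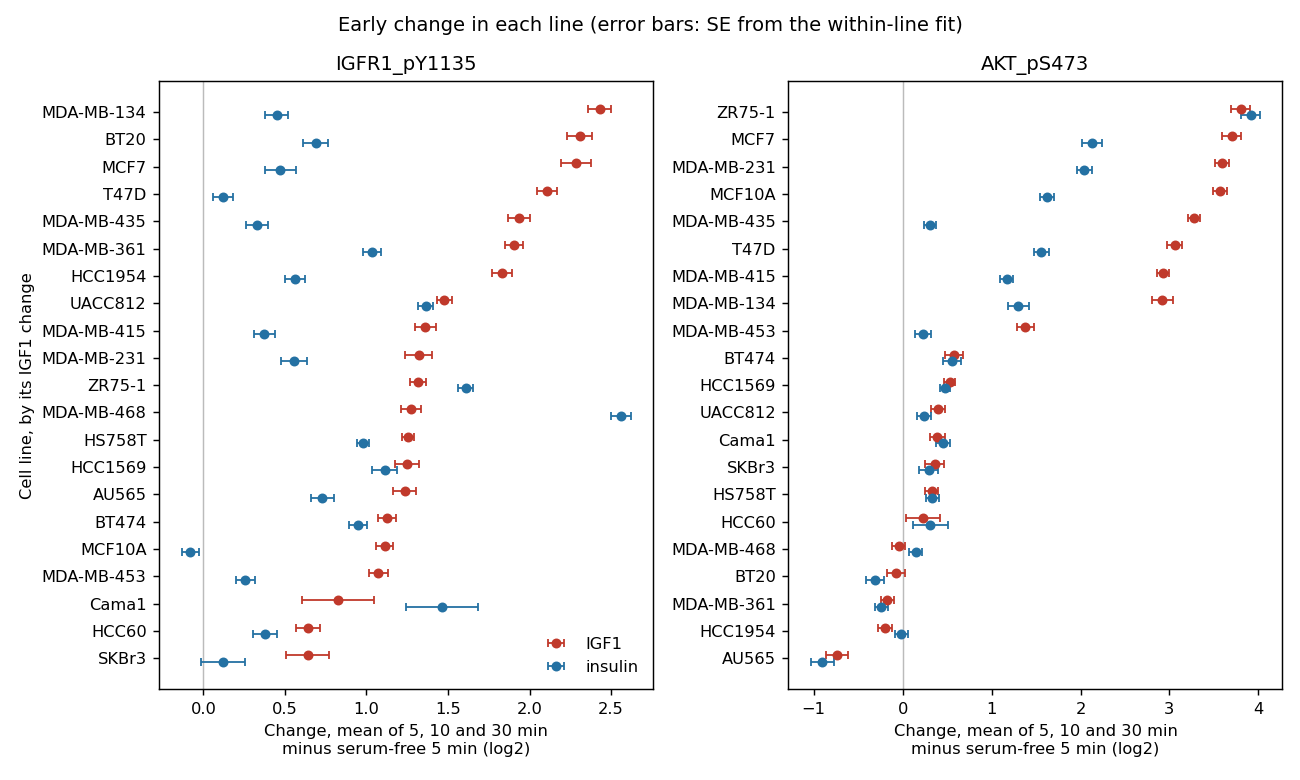
Early change of IGFR1_pY1135 (left) and AKT_pS473 (right) in each of 21 lines, in log2 on the x axis, with IGF1 in red and insulin in blue; lines are ordered by their IGF1 change and bars are SE from the fit within the line. IGFR1_pY1135 in MDA-MB-468 stood at 2.56 with insulin, while AKT_pS473 with IGF1 ran from -0.74 in AU565 to 3.80 in ZR75-1.

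The size of the response depended strongly on the line. By limma's F-test 115 of 134 antibodies differed between lines in their early IGF1 change, and Akt led (F = 259 for AKT_pS473). AKT_pS473 rose by 3.80 in ZR75-1, 3.70 in MCF7 and 3.59 in MDA-MB-231, and stood at -0.74 in AU565, -0.20 in HCC1954 and -0.17 in MDA-MB-361. AKT_pT308 (F = 120) ranged from 2.44 in MCF7, 2.42 in ZR75-1 and 2.33 in T47D to 0.04 in HS758T, -0.26 in MDA-MB-361 and -0.52 in AU565. STAT5_pY694 (F = 103) ranged from 3.02 in MCF7, 1.68 in T47D and 1.59 in MDA-MB-415 to 0.03 in Cama1, -0.07 in MDA-MB-361 and -0.40 in HCC1954. The F-test assumes 1 spread for all lines, and with each line's own spread 128 antibodies differed.

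The difference between the hormones also depended on the line, for 28 antibodies (38 with each line's own spread). IGFR1_pY1135 (F = 205) was higher with IGF1 by 1.99 in T47D, 1.98 in MDA-MB-134 and 1.81 in MCF7, and higher with insulin in MDA-MB-468 (-1.28), Cama1 (-0.64) and ZR75-1 (-0.29). AKT_pS473 (F = 172) was higher with IGF1 by 2.97 in MDA-MB-435, 1.94 in MCF10A and 1.76 in MDA-MB-415, and stood at -0.19 in MDA-MB-468, -0.19 in HCC1954 and -0.11 in ZR75-1. AKT_pT308 (F = 92.9) ran from 1.53 in MCF10A, 1.38 in MCF7 and 1.35 in T47D to -0.13 in ZR75-1, -0.18 in MDA-MB-468 and -0.20 in BT474. Without replicate 1 the count of antibodies whose difference depended on the line was 63.

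**Figure D3:**
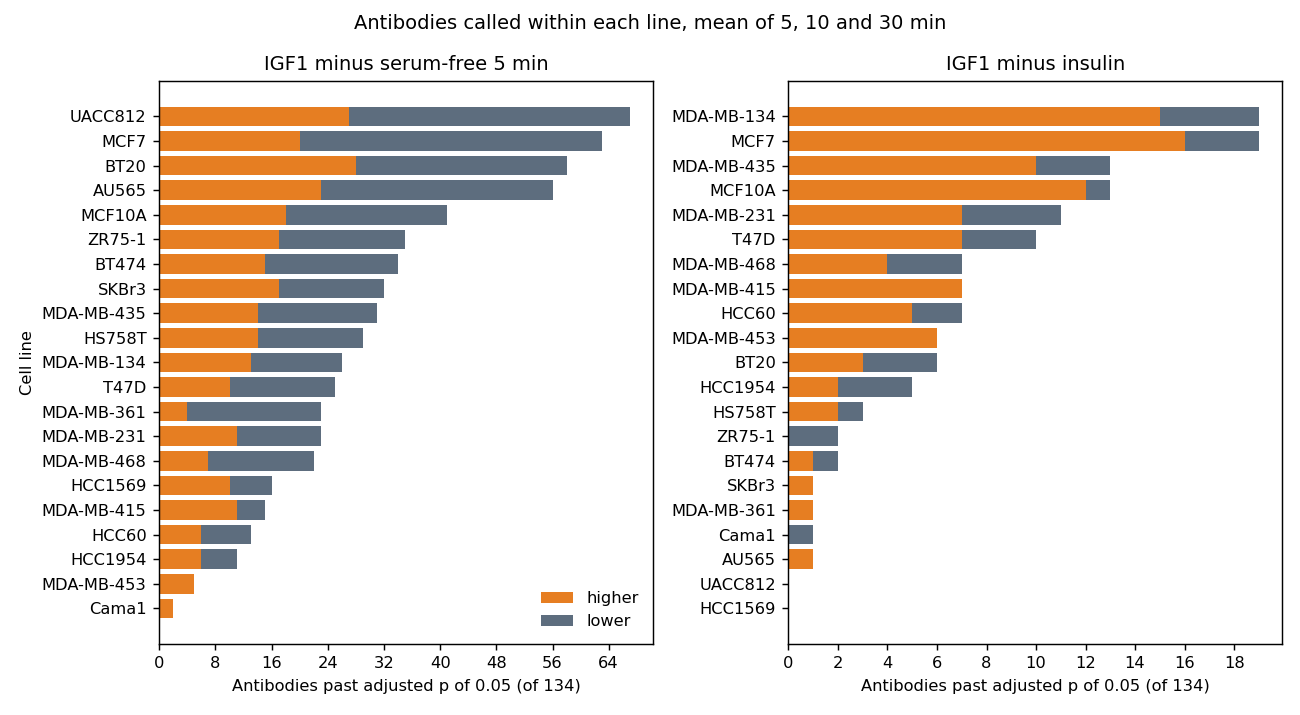
Number of antibodies (x axis, of 134) past an adjusted p of 0.05 within each of 21 lines, higher in orange and lower in grey, for early IGF1 against serum-free 5 min (left) and early IGF1 against insulin (right). UACC812 had 67 calls for IGF1 and 0 between the hormones, and MCF7 had 63 and 19.

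Within single lines, 627 of 2814 pairs of line and antibody passed for early IGF1, 278 higher and 349 lower, spread over 129 antibodies. UACC812 had most calls with 67, then MCF7 with 63 and BT20 with 58; Cama1 had 2, MDA-MB-453 5 and HCC1954 11. IGFR1_pY1135 was called higher with IGF1 in 21 of 21 lines and AKT_pS473 in 15, with 1 lower. For early insulin 657 pairs passed, 309 higher and 348 lower, over 132 antibodies, against the same serum-free dishes. UACC812 then had 76 calls, BT20 67 and MCF7 54. An offset of these shared dishes would enter both counts and cannot be told from a ligand effect. The insulin count was added after seeing the data. Between the hormones 134 pairs passed, 100 higher with IGF1 and 34 lower, over 38 antibodies. MDA-MB-134 and MCF7 had 19 calls each, MCF10A and MDA-MB-435 13 each, and UACC812 and HCC1569 0; AU565, Cama1, MDA-MB-361 and SKBr3 had 1 each. IGFR1_pY1135 was called higher with IGF1 in 16 lines and with insulin in 3, and AKT_pS473 in 9 and 2. The share of higher calls moved with the loading correction. Without it the early IGF1 calls were 625 higher and 70 lower, and those of early insulin 585 and 89, and those between the hormones 62 and 11; with loading by total proteins the early IGF1 calls were 299 and 279. Cama1 and MDA-MB-453 also held 9 and 8 of the 19 dishes with extreme loading. Without replicate 2 or without replicate 3 348 pairs passed for early IGF1, and 291 or 374 for early insulin; between the hormones 211 passed without replicate 1.

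At 6 h of IGF1 the signals of the phosphorylated receptor, Akt and ribosomal protein S6 lay above the starting control, while ERK and ACC phosphorylation lay below it. IGFR1_pY1135 rose by 1.39 ± 0.11 in 21 lines (limma adjusted p = 1.09e-09), AKT_pS473 by 1.18 ± 0.27, AKT_pT308 by 0.51 and GSK3ab_pT21 by 0.23. S6_pS240 rose by 0.73 ± 0.19 in 15 lines (adjusted p = 0.0152) and S6_pS235 by 0.60 ± 0.17, and the mTOR-S6K list by 0.28 ± 0.09 (permutation adjusted p = 0.00951), with 2 of 6 members called and 3 adjusted over the list alone. STAT5_pY694 rose by 0.79 and STAT6_pY641 by 0.32. MAPK_pT202 fell by 0.79 ± 0.24 in 16 lines (adjusted p = 0.0283), MEK12_pS217 by 0.16, p38_pT180 by 0.18, STAT3_pT727 by 0.17 and IRB_2, an insulin receptor antibody, by 0.15. ACC_pS79, the AMPK site of acetyl-CoA carboxylase, fell by 0.32 ± 0.06 in 17 lines (adjusted p = 0.00199). In all 8 rose and 6 fell, and 33 had an unadjusted p under 0.05.

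Other list means also passed at 6 h of IGF1. The PI3K-Akt list rose by 0.41 ± 0.10 (3 of 5 members, 4 adjusted over the list alone), and the receptor and adaptor list by 0.13 ± 0.02 against a member median of -0.09 (1 up, 1 down). The MAPK list mean was -0.36 ± 0.10 (0 up, 2 down), stress kinases -0.10 ± 0.03 (1 of 2 down) and energy sensing -0.10 ± 0.03 (1 of 4 down). Src-STAT-FAK stood at 0.08 ± 0.02 (2 up, 1 down; member median 0.00, just below 0), and adhesion and mesenchymal proteins at -0.04 ± 0.02 with 0 of 7 called; each of these passed (permutation adjusted p of 0.0149 or less). The stress kinase, energy sensing, Src-STAT-FAK and adhesion lists did not pass without the loading correction (0.566, 0.566, 0.169 and 0.887), nor the last with loading by total proteins (0.0935).

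Insulin for 6 h raised phosphorylated STAT5, the receptor signal and Akt, and ERK phosphorylation lay below the starting control. STAT5_pY694 rose by 0.57 ± 0.11 in 21 lines (limma adjusted p = 0.00367), IGFR1_pY1135 by 0.47 ± 0.10 in 21, AKT_pS473 by 0.51 ± 0.15 in 18 (adjusted p = 0.0346) and STAT6_pY641 by 0.26. The ErbB receptor sites HER2_pY1248 and EGFR_pY1173 rose by 0.23 ± 0.07 and 0.20 ± 0.06, and their list by 0.12 ± 0.04 (2 of 5 members). Cyclin.D1, which drives entry into S phase, rose by 0.13, CHK2_pT68 by 0.08 and total TSC2 by 0.06. MAPK_pT202 fell by 0.96 ± 0.21 in 18 lines (adjusted p = 0.00367), ACC_pS79 by 0.25, p38_pT180 by 0.18, STAT3_pT727 by 0.18 and MEK12_pS217 by 0.14. S6_pS240 stood at 0.42 ± 0.14 (adjusted p = 0.0512). In all 9 rose and 5 fell, and 30 had an unadjusted p under 0.05. List means were 0.18 ± 0.06 for PI3K-Akt, -0.41 ± 0.09 for MAPK, -0.12 ± 0.03 for stress kinases, -0.07 ± 0.02 for energy sensing and 0.07 ± 0.02 for Src-STAT-FAK (permutation adjusted p of 0.023 or less). Of these and the ErbB list, the MAPK list alone passed without the loading correction (0.316 or more for the others).

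These 6 h values rest on a control labelled 5 min. Against serum-free 24 h instead, 7 rose and 4 fell with IGF1, 7 of the 14 calls being shared, and 4 rose and 3 fell with insulin, 3 shared. MAPK_pT202 then stood at -0.08 with IGF1 and -0.24 with insulin (limma adjusted p = 0.872 and 0.288, n = 21 lines), and EGFR_pY1173 and CHK2_pT68 with insulin at -0.0036 and -0.0079. The calls of p38_pT180, STAT3_pT727, MEK12_pS217 and STAT6_pY641 ended for both hormones. With IGF1 those of AKT_pT308 and GSK3ab_pT21 ended narrowly (limma adjusted p = 0.0571 and 0.0529). With insulin those of AKT_pS473 (0.0776), Cyclin.D1 (0.103), TSC2 (0.487) and HER2_pY1248 (0.881) ended. Without the loading correction 8 rose and 2 fell with IGF1, and 2 rose and 1 fell with insulin; 10 and 3 of the 14 calls remained, the 3 being STAT5_pY694, IGFR1_pY1135 and MAPK_pT202; AKT_pS473 with insulin had adjusted p = 0.0605 then and 0.204 in 1 fit of all line means, which also ended the calls of CHK2_pT68 and TSC2 (0.146 and 0.18). With IGF1 the calls of p38_pT180, STAT3_pT727 and MEK12_pS217 ended without the correction (0.424, 0.546 and 0.465), the latter 2 also with loading by total proteins (0.0715 for both). The IRB_2 fall with IGF1 was among those lost (limma adjusted p = 0.644). It also lost its call with medians of dishes (0.128), with replicates kept separate (0.0803) or without replicate 2 (0.121). With IGF1, GSK3ab_pT21 lost its call without replicate 2 and MEK12_pS217 without replicate 1. With insulin, EGFR_pY1173, CHK2_pT68 and TSC2 lost theirs without replicate 2, and Cyclin.D1 without replicate 3. With the mean as loading measure the splits were 8 and 12, and 7 and 6, with EGFR_pY1173 and CHK2_pT68 lost with insulin (0.0506 and 0.0693). With replicates kept separate they were 14 and 8, and 16 and 7. MAPK_pT202 with IGF1 lost its call without any 1 of AU565, BT20, SKBr3, UACC812 or ZR75-1 (adjusted p up to 0.0618), and AKT_pS473 with insulin without HCC60, HS758T, MCF10A, MDA-MB-134, MDA-MB-231 or ZR75-1 (up to 0.0642).

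Calls that ended without single lines at 6 h were further those of STAT3_pT727 with IGF1 (AU565, BT20, SKBr3, UACC812; adjusted p up to 0.0561, n = 20 lines) and MEK12_pS217 with IGF1 (the same 4 lines, MDA-MB-231, MDA-MB-415 and MDA-MB-435; up to 0.0696). With insulin, HER2_pY1248 depended on AU565, HCC1954, MDA-MB-361, SKBr3 and UACC812 (limma adjusted p up to 0.063). EGFR_pY1173 depended on BT474, HCC1954, MDA-MB-361, MDA-MB-468, SKBr3 and UACC812 (up to 0.0684), and Cyclin.D1 on MDA-MB-134, MDA-MB-231, SKBr3 and ZR75-1 (up to 0.0542).

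Averaged over 24 and 48 h, the phosphorylated receptor signal with IGF1 lay above the time-matched control, and receptor proteins were lower. The mean of the 2 times for IGFR1_pY1135 rose by 0.51 ± 0.08 in 21 of 21 lines (limma adjusted p = 0.000214). The insulin receptor antibodies IRB and IRB_2 fell by 0.19 ± 0.04 in 18 lines (adjusted p = 0.00352) and by 0.17 ± 0.04 in 16 (adjusted p = 0.0402), and IGFR1B fell by 0.13 ± 0.03 in 17 lines (adjusted p = 0.0402). Of the 7 receptor and adaptor antibodies 1 rose and 3 fell, the same numbers adjusted over the list alone. AKT_pS473 stood at 0.33 ± 0.10 (adjusted p = 0.0831) and S6_pS240 at 0.16. The Src-STAT-FAK list rose by 0.04 ± 0.01 and the PKC list fell by 0.05 ± 0.01 (permutation adjusted p = 0.0193 for both), with 0 members called in either; neither passed without the loading correction (0.396 and 0.778), nor PKC with loading by total proteins (0.0658). In all 1 rose and 3 fell, with 20 at an unadjusted p under 0.05. Without the loading correction 2 rose and 2 fell, with loading by total proteins 3 and 3, and with replicates kept separate 10 and 4. IRB and IRB_2 are marked N in the quality column, and with antibodies marked Y alone 1 was called. The count was 7 without BT474 and 2 without any 1 of HCC1569, HS758T, MCF10A, MDA-MB-134, MDA-MB-231, MDA-MB-361, MDA-MB-415, MDA-MB-435, MDA-MB-453, T47D or ZR75-1, when IRB_2 and IGFR1B lost their calls (adjusted p up to 0.0922 and 0.0845). IRB_2 lost its call without MCF7, replicate 1 or replicate 2 too, and IGFR1B without the loading correction (adjusted p = 0.211), replicate 3 or with antibodies marked Y alone (0.0572).

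Late insulin called 0 of 134 antibodies by limma or the sign-flip test, with 2 at an unadjusted p under 0.05. IGFR1_pY1135 stood at 0.14 ± 0.06 and IRB at -0.08 ± 0.03 (limma adjusted p = 0.965 for both). Directly compared at late times, STAT5_pY694 was 0.18 ± 0.04 higher with IGF1 than with insulin in 17 lines and IRB_2 stood at -0.15 ± 0.03, lower in 19 (limma adjusted p = 0.0164 for both), with 19 at an unadjusted p under 0.05. IGFR1_pY1135 stood 0.37 ± 0.11 higher, AKT_pS473 0.28 ± 0.08 higher and IGFR1B at -0.10 ± 0.03 (adjusted p = 0.0572 for each). Without the loading correction 2 were higher and 0 lower, and IRB_2 had limma adjusted p = 0.0853. With the mean as loading measure 1 was higher and 3 lower, and with replicates kept separate 7 and 3. The count was 6 without HCC60, 5 without MDA-MB-468, 4 without UACC812, 1 without the weakest 25% of antibodies, and 0 with antibodies marked Y alone, since both are marked N. STAT5_pY694 lost its call in 1 fit of all line means (adjusted p = 0.927).

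The early IGF1 change lay above the late one for 6 antibodies. The early change exceeded the late one by 1.09 ± 0.26 for AKT_pS473 in 18 lines (limma adjusted p = 0.0134), 0.95 ± 0.10 for IGFR1_pY1135 in 21 lines (adjusted p = 1.79e-07) and 0.63 ± 0.17 for AKT_pT308. It exceeded it by 0.36 for STAT5_pY694, 0.18 for STAT6_pY641 and 0.18 for IRB, which stood at -0.01 early and -0.19 late. Total GSK3ab was the 1 antibody with a lower early change, by -0.13 ± 0.04 (adjusted p = 0.0365). The receptor and adaptor list differed by 0.19 ± 0.02 and the PI3K-Akt list by 0.39 ± 0.11 (permutation adjusted p = 0.00015 and 0.009). Of 134 antibodies 23 had an unadjusted p under 0.05. Without the loading correction 6 were higher and 0 lower early, with the mean as loading measure 6 and 2, and with replicates kept separate 9 and 5. Medians of dishes called 4, and 1 fit of all line means and antibodies marked Y alone called 3 each. The count fell to 3 without MCF7, MCF10A, MDA-MB-134, T47D or ZR75-1 and to 4 without MDA-MB-231, MDA-MB-415 or MDA-MB-435; AKT_pT308 and STAT5_pY694 lost their calls without each of these 8 lines (adjusted p up to 0.0623 and 0.0607). STAT6_pY641 lost it without MCF7, MCF10A, MDA-MB-134, MDA-MB-415, T47D or ZR75-1 (up to 0.0607), and GSK3ab without MCF7, MCF10A, MDA-MB-134, MDA-MB-231, MDA-MB-361, MDA-MB-435, T47D, UACC812 or ZR75-1 (up to 0.0832). The GSK3ab call also ended without the loading correction (adjusted p = 0.791), with medians of dishes (0.0569), 1 fit of all line means (0.0952), antibodies marked Y alone (0.0508), without dishes of extreme loading (0.0562), and without replicate 1 or 3. In that 1 fit STAT5_pY694, STAT6_pY641 and IRB lost theirs too (0.0952, 0.112 and 0.0722), and medians of dishes ended those of STAT5_pY694 and STAT6_pY641 (0.053 for both), as did leaving out replicate 1 for the former and the loading correction for the latter (0.0536).

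Longer culture without serum or ligand raised 2 antibodies to apoptosis proteins and lowered antibodies to phosphorylated ERK, S6 and Rb. From serum-free 5 min to 48 h, PARP_2, a PARP1 antibody, rose by 0.57 ± 0.13 in 19 lines (limma adjusted p = 0.0147) and Caspase.7, an executioner caspase, by 0.41 ± 0.09 in 20 lines (adjusted p = 0.00962). The file's quality column marks Caspase.7 N. The other PARP1 antibody, PARP, stood at 0.02 (adjusted p = 0.801) and Caspase.3 at 0.10 (adjusted p = 0.262). MAPK_pT202 fell by 0.74 ± 0.19 in 15 lines (adjusted p = 0.0244), S6_pS240 by 0.59 ± 0.15 and S6_pS235 by 0.50 ± 0.13 (adjusted p = 0.0207 for both). Rb_pS807, the phosphorylated form of the retinoblastoma protein found in cycling cells, fell by 0.37 ± 0.11 in 16 lines; total Rb stood at -0.22 ± 0.07 (adjusted p = 0.063, and called over the cell cycle list alone), so a change in the phosphorylated share is not shown. STAT3_pT727 fell by 0.17 in 15. At 24 h MAPK_pT202 already stood at -0.72 ± 0.17 and Caspase.7 at 0.19 ± 0.04 (adjusted p = 0.0173 for both). The apoptosis and survival list rose by 0.19 ± 0.04 (2 of 7 members), ErbB receptors by 0.11 ± 0.04 (0 of 5) and Src-STAT-FAK by 0.05 ± 0.02 (0 up and 1 down of 11; -0.02 without the loading correction). The mTOR-S6K list mean was -0.27 ± 0.07 (2 of 6 down), MAPK -0.36 ± 0.09 (1 of 3 down) and cell cycle -0.13 ± 0.03 (1 of 10 down, 3 adjusted over the list alone), all with a permutation adjusted p of 0.0203 or less. The MAPK list alone passed without the loading correction (0.122 for mTOR-S6K and 0.46 or more for the others), and with loading by total proteins ErbB receptors and Src-STAT-FAK did not (0.0732 and 0.212).

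In all, 2 antibodies rose and 5 fell by 48 h without serum, with 27 at an unadjusted p under 0.05. With the mean as loading measure 2 rose and 3 fell, and with replicates kept separate 7 rose and 10 fell. A single fit of all line means called 28 (11 up, 17 down). Without the loading correction 1 rose and 3 fell, and the calls of Caspase.7, Rb_pS807 and STAT3_pT727 ended (limma adjusted p = 0.0827, 0.0668 and 0.442). Rb_pS807 also lost its call with loading by the mean (0.0543), medians of dishes (0.0544), the sign-flip test (0.0634) and without replicate 1 or 2, and STAT3_pT727 with loading by the mean (0.061) and without replicate 2 or 3. The count was 13 without MCF10A and 4 without BT474, SKBr3 or ZR75-1, when MAPK_pT202 lost its call (adjusted p up to 0.0553). Rb_pS807 kept its call in 6 and STAT3_pT727 in 9 of the 21 fits that each left out 1 line (adjusted p up to 0.0882 and 0.087).

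Lines whose AKT_pS473 rose most with early IGF1 started with more IRS1 and IGFR1B on average. The early IGF1 change divided the lines into 8 with a change of 2.92 or more and 13 with 1.38 or less. Baseline IRS1 was 1.73 ± 0.96 (SD, n = 8 lines) in the former and 0.34 ± 0.45 (n = 13) in the latter, a difference of 1.40 ± 0.36 (SE; two-sided exact permutation p = 0.000113, adjusted p = 0.000452 over 4 tests). It was 0.70 or more in all 8, and 0.59 or less in all of the 13 but MDA-MB-453 (1.51). IGFR1B was 0.68 ± 0.20 higher in the 8 lines (exact permutation p = 0.000663, adjusted p = 0.00111). The groups overlapped, with IGFR1B at -1.28 in BT20 of the 13 and -1.82 in ZR75-1 of the 8. IGFR1B was 0.67 ± 0.21 higher in the 8 lines with the larger difference between the hormones in AKT_pS473 (exact permutation p = 0.000831, adjusted p = 0.00111). Without the loading correction these IGFR1B differences were 0.58 and 0.63 (exact permutation adjusted p = 0.0321 and 0.027). E.Cadherin stood at -0.21 ± 0.62 between the groups of the IGF1 change (exact permutation p = 0.75, adjusted p = 0.75). These 4 tests were added after seeing the data, on groups drawn from the same data, and baseline and change share the serum-free 5 min dishes. Baseline AKT_pS473 also differed in level between the groups, at -0.80 or less in the 8 lines and -0.30 or more in 12 of the 13, so the measures cannot be separated here. Without the 2 lines farthest from the median the differences were 0.92 for IRS1 and 0.43 and 0.42 for IGFR1B (exact permutation adjusted p = 0.00339, 0.0111 and 0.0111).

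In the planned family of 12 correlations across lines none passed after adjustment. Of these, 8 were computed within such groups, which were cut on the response itself, so they say nothing of a difference between the groups. Within them IGFR1B against the early IGF1 change of AKT_pS473 gave r = -0.141 (permutation p = 0.633, n = 13 lines) and r = -0.034 (exact permutation p = 0.934, n = 8 lines), with rho = -0.198 and -0.286 (permutation p = 0.519 and 0.501). IRS1 gave r = 0.533 (permutation p = 0.0711, n = 13 lines; rho = -0.044, permutation p = 0.89), which rests on MDA-MB-453 and BT20 (r = -0.188 without them), and r = -0.074 (exact permutation p = 0.843, n = 8 lines; rho = -0.095, exact permutation p = 0.84). Over all 21 lines, baseline IRS1 against the early insulin change of AKT_pS473 gave r = 0.584 (permutation p = 0.00809, adjusted p = 0.0971; rho = 0.591, permutation p = 0.00556, adjusted p = 0.0667), and r = 0.539 without MCF7 and T47D. Baseline PTEN against baseline AKT_pS473 gave r = -0.226 (permutation p = 0.33, n = 21 lines) and rho = -0.212 (permutation p = 0.356). Without the loading correction the difference between the hormones left the lines undivided, and baseline IGFR1B against it gave r = 0.549 (permutation p = 0.00999, adjusted p = 0.11, n = 21 lines; rho = 0.588, permutation p = 0.00608, adjusted p = 0.0669), and r = 0.459 without MCF7 and MDA-MB-134.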

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

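The counts over regrouped samples, the relation of receptor levels to the hormone difference, the tests of an upper signal limit, of time in serum-free medium and of loading were chosen after the results were seen. The tests of exchanged ligand labels, of an antibody that also detects insulin receptor and of whether the ligand acted were written before their values were seen.

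Lines differed in how they answered the hormones, which is why the values here are listed. The early IGF1 change differed between lines for 115 antibodies, led by AKT_pS473 (F = 259.0), AKT_pT308 (F = 120.0) and STAT5_pY694 (F = 102.6). The early difference between IGF1 and insulin differed between lines for 28 antibodies, led by IGFR1_pY1135 (F = 205.0), AKT_pS473 (F = 172.0) and AKT_pT308 (F = 92.9). The early and late changes with IGF1 differed for 7 antibodies. The early change minus the late one was 1.09 for AKT_pS473, 0.95 for IGFR1_pY1135, 0.63 for AKT_pT308, 0.36 for STAT5_pY694, 0.18 for STAT6_pY641, 0.18 for IRB and -0.13 for GSK3ab.

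In MDA-MB-468 insulin raised IGFR1_pY1135 more than IGF1 did, with a difference of -1.28 log2, against the direction of 18 of the 21 lines. Receptor levels of the other 20 lines predicted -1.03 for this line (95% interval -2.29 to 0.24), which holds the value as labelled and not its opposite, so exchanged ligand labels are argued against; the prediction reaches beyond the other lines' range of receptor levels. More insulin receptor relative to IGF1 receptor than in other lines may account for it, since baseline IGFR1B minus IRB correlated with the difference over the other 20 lines (r = 0.783, permutation p = 5e-05, adjusted p = 1e-04; rho = 0.711, permutation p = 0.00062; r = 0.719 without ZR75-1 and T47D); each antibody has its own scale, so this difference ranks lines and does not show which receptor a line holds more of. An antibody that also detects the phosphorylated insulin receptor stays open: baseline IRB correlated with the early insulin change (r = 0.575, permutation p = 0.00721, n = 20 lines; rho = 0.390, permutation p = 0.0926), but this rests on ZR75-1 and HCC60 (r = 0.376 without them, permutation p = 0.123). These relations were found and tested on the same data. They and the prediction for MDA-MB-468 rest on IRB, which the file's quality column marks N.

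In 12 lines the upper 95% bound of the early IGF1 change of AKT_pS473 lay below 1 log2; it was called higher in 6 of them (BT474 0.57, HCC1569 0.53, UACC812 0.39, Cama1 0.39, SKBr3 0.36, HS758T 0.33), lower in AU565 and neither in 5. A signal at its upper limit is argued against for Cama1, HCC60, HCC1569, HS758T and UACC812 (5 lines). Their baseline lay at least 1 log2 below the antibody's 95th percentile of 2.15. AU565, nearer that level, fell by 0.74 (upper 95% bound -0.4755). This fall is in values corrected for loading, and the offsets of AU565 dishes ran from 0.17 to 1.27 log2. A rise in offset would lower the corrected value of a signal at its limit, so the limit stays open for AU565. For the other 6 near that level the limit stays open: BT474 and SKBr3 rose, so a limit there would bear on the size alone, HCC1954 and MDA-MB-361 stood at -0.20 and -0.17 (upper bounds -0.04 and -0.02, adjusted p = 0.104 and 0.122), and GSK3ab_pT21, called higher in 0 of the 6, does not bear on the range of the Akt antibody. A ligand that did not act is argued against, since IGFR1_pY1135 was called higher in 12 of the 12 lines (0.64 to 2.31 log2). Line-specific Akt regulation remains untested.

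MAPK_pT202 at 6 h lay below serum-free 5 min with IGF1 and with insulin. The loading correction is argued against as the cause, since without it the changes were -0.76 with IGF1 (upper 95% bound -0.29) and -0.96 with insulin (upper bound -0.60). A fall with time in serum-free medium is consistent with the values. Without ligand MAPK_pT202 stood at -0.72 ± 0.17 at 24 h, and against those dishes the 6 h values were -0.0764 ± 0.156 with IGF1 and -0.243 ± 0.118 with insulin (limma adjusted p = 0.872 and 0.288). No serum-free dishes at 6 h exist, so an effect of either hormone on ERK at that time remains untested.

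Regrouping asked how often random regroupings of the same samples give as many calls, the real one included, in 100 for each result. For comparisons over lines the difference was turned in randomly drawn lines. Few regroupings gave as many calls for early IGF1 (2 of 100, real 7, highest other 9), IGF1 at 6 h (1 of 100, 14 against 2), insulin at 6 h (1 of 100, 14 against 0) and late IGF1 (1 of 100, 4 against 3). The same held for IGF1 minus insulin late (2 of 100, 2 against 3), IGF1 early minus late (1 of 100, 7 against 1) and serum-free 48 h minus 5 min (1 of 100, 7 against 0). For early IGF1 and IGF1 minus insulin late a regrouping gave more calls than the real data. These shares are not adjusted over the results tested, so chance is made less likely but not excluded. Early insulin reached its count in 6 of 100 (1 against 3), so chance cannot be excluded there either. Late insulin (0; highest other 4) and IGF1 minus insulin early (0; highest other 7) had no calls, so all 100 of 100 regroupings give as many by design and the counts say nothing about chance.

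Taken over the 6 times together, the calls of IGF1 (1 of 100, 33 against 20), insulin (1 of 100, 19 against 9) and IGF1 minus insulin (1 of 100, 8 against 4) exceeded those of all other regroupings. With dishes shuffled within lines, no other regrouping gave as many calls within lines for early IGF1 (1 of 100, 627 against 149). The same held within lines for early insulin (1 of 100, 657 against 128) and IGF1 minus insulin (1 of 100, 134 against 58). It held for the differences between lines in early IGF1 change (1 of 100, 115 against 58) and in IGF1 minus insulin (1 of 100, 28 against 11). With dishes shuffled among lines it held for baseline levels too (1 of 100, 133 against 2). These shares too are not adjusted over the results tested, so chance is made less likely but not excluded. Shuffling also cannot tell a ligand effect from an offset of the serum-free dishes that early IGF1 and early insulin share.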

How the results depend on the processing

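Counting early insulin within lines, comparing baseline levels between response groups, restricting to antibodies marked Y, leaving out dishes with extreme loading, the Welch version of the test between lines and the loading alternatives at each time were chosen after seeing the data. Of 56 named calls, 37 held without any 1 line and 42 without any 1 replicate number. The cause of the moves below was not tested, except that fewer dishes or antibodies enter some settings. Without loading correction the calls were 7 for early insulin (main value 1), 3 for insulin at 6 h (14), 4 for serum-free 48 h (7), 73 within lines between the hormones (134) and 18 list shifts (34). Values then turned to 0.0364 for SMAD3, 0.0399 for the energy sensing and 0.0634 for the adhesion and mesenchymal list with early IGF1, and -0.0179 for Src-STAT-FAK at serum-free 48 h. With loading by the mean, 13 were called for early IGF1 (7), 2 for early insulin and 4 for IGF1 minus insulin late (2), which had 1 when the weakest 25% of antibodies were left out instead. Medians of dishes gave 4 for early minus late (7). A single fit of all line means gave 4 for early insulin, 5 for IGF1 minus insulin early (0), 3 for early minus late and 28 for serum-free 48 h; the sign-flip test gave 2 for early insulin. With the mean of 3 serum-free times as control, early IGF1 had 36 and early insulin 14, and MAPK_pT202 with early IGF1 stood at 0.41. With serum-free 24 h as control insulin at 6 h had 7, EGFR_pY1173 -0.0036 and CHK2_pT68 -0.0079. Antibodies marked Y alone gave 1 for late IGF1 (4), 0 for IGF1 minus insulin late and 3 for early minus late. Without dishes of extreme loading the counts were the same except 6 for early minus late. Late insulin had 0 in every setting. With each line's own spread, 128 and 38 antibodies differed between lines (115 and 28).

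Without 1 line at a time counts ran from 4 to 10 for early IGF1, 1 to 4 for early insulin, 11 to 15 and 11 to 16 for IGF1 and insulin at 6 h, 2 to 7 for late IGF1, 0 to 3 for IGF1 minus insulin early, 2 to 6 for it late, 3 to 9 for early minus late and 4 to 13 for serum-free 48 h. Without 1 replicate number they ran from 1 to 2 for early insulin, 0 to 2 for IGF1 minus insulin early, 348 to 587 within lines for early IGF1, 291 to 623 for early insulin (657), 93 to 211 between the hormones, and 22 to 63 for its differences between lines. Replicate numbers do not pair the dishes: same-numbered deviations correlated at -0.014 on average, 1646 of 6615 pairs exceeded 0.1, and 217 dishes correlated best with their own number. With replicates kept separate and the line as block, counts were 14 for early IGF1, 7 for early insulin, 22 and 23 for IGF1 and insulin at 6 h, 14 for late IGF1, 0 for late insulin, 11 and 10 for IGF1 minus insulin early and late, 14 for early minus late and 17 for serum-free 48 h. With the replicate number as a block they were 613 and 137 within lines, 641 within lines for early insulin, and 115 and 28 between lines. The pseudocount alternative was not run, since values are already log2. Signal over background is not in the file, so weak antibodies cannot be told from background.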

Other observations

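The values below were chosen after they were seen. Against serum-free 5 min, MAPK_pT202 moved in opposite directions in different lines with either hormone. Within lines it was called higher in 6 and lower in 7 of 21 with early IGF1 (F = 45.5 for the difference between lines), and higher in 7 and lower in 10 with early insulin, against the same serum-free dishes. With IGF1 it rose by 1.92 ± 0.13 in MCF7, 0.91 ± 0.10 in T47D and 0.76 ± 0.15 in ZR75-1 (SE from 45 dishes per line). It stood at -1.38 ± 0.12 in SKBr3, -1.37 ± 0.10 in MDA-MB-361 and -1.01 ± 0.19 in MDA-MB-468. With insulin it stood at 0.86 ± 0.15 in ZR75-1, 0.52 ± 0.13 in MCF7, -1.36 ± 0.12 in SKBr3 and -1.47 ± 0.10 in MDA-MB-361. Between the hormones it was called in 4 lines, higher with IGF1 by 1.40 in MCF7, 0.90 in MCF10A, 0.56 in MDA-MB-134 and 0.54 in T47D. These values rest on 1 control: against the mean of 3 serum-free times the mean early IGF1 change over lines was 0.41 (adjusted p = 0.0443), and in MDA-MB-361 MAPK_pT202 fell by 3.36 from 5 min to 48 h without ligand.

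In MCF7 the phosphorylated receptor signal was not above the control at 24 h of IGF1 and was above it at 48 h, while STAT5 and Akt phosphorylation lay above it at both times. IGFR1_pY1135 in MCF7 was -2.47 ± 0.04 (SD, n = 3 dishes) at 24 h of IGF1 against -2.38 ± 0.03 in serum-free medium, and -0.85 ± 0.18 at 48 h against -2.46 ± 0.08. STAT5_pY694 was 0.68 ± 0.19 at 24 h against 0.09 ± 0.03, and 2.73 ± 0.07 at 48 h against -0.03 ± 0.11. AKT_pS473 was -0.86 ± 0.17 at 24 h against -1.55 ± 0.04, and 0.84 ± 0.05 at 48 h against -1.22 ± 0.15.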
